A study of Solanum tuberosum with 97 samples.

How the data were processed

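RNA-seq was made from tubers of the potato cultivar Russet Burbank, in primary meristem, secondary meristem and flesh, at 0, 3, 6, 9 and 12 weeks of storage. Tubers were untreated or had received 1, 2 or 3 applications (1x, 2x, 3x) of 1,4-dimethylnaphthalene (DMN), a vapour used to hold back sprouting in store. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned with HISAT2, handled with SAMtools and counted with StringTie. The versions, settings, genome build and annotation release are not given in the sources used here, nor is the use of strand, so genes that overlap or have near-identical copies may share reads.

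The deposited values are counts per gene in 1 table and counts per transcript in another, with no normalization. The gene table held 97 columns and 32878 genes, and the transcript table held 44851 transcripts of 32917 genes. Each gene column was compared with the transcript counts of the same group summed per gene. In 9 of the 97 columns the values were averages of libraries of the group, to within 1 count in at least 99.96% of genes. Of these, 8 averaged 2 libraries and 1 averaged 3. In 1 of them, a secondary meristem column of week 6, the deposited values are not whole numbers: they are estimated counts that weight 2 libraries by 0.25 and 0.75. The transcript table held 97 libraries, of which 9 have no gene column of their own. The 9 averaged columns were left out, which leaves 88 libraries in 33 groups. The column that averaged 3 libraries and the weighted one each contain part of a library with no other gene column, so leaving them out gives up those counts. All 9 libraries enter in full only where the transcript table is summed, and the use of all 97 columns takes in those parts. This was decided after the columns had been seen, and the use of all 97 columns is among the alternatives. As deposited, 39 genes with up to 3.59% of a library's counts were found only in the transcript table.

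Of 2893264 values in the 88 columns, 1107393 were 0, 6 were 1, 385 were 2 and 2381 were 3, against 9487 values of 10. Counts of 1 to 3 were thus nearly absent, and no source used here records why. A 0 is therefore described as listed at 0, with the level in the other group and no fold change. Gene names are the deposited annotation text, present for 27071 genes with an informative description. The reference gene table matched 0 identifiers, so no other names or positions were used.

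Total counts per library, in units of 1e6 (M), ran from 22.5 to 44.8 M, with a median of 31.1 M. The labels do not say whether replicates were separate tubers, so p-values measure the spread between these samples. The labels give no sequencing batch or date.

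Counts were analysed in R 4.3.3 with edgeR 4.0.16. One model per tissue had 1 coefficient per group of week and treatment, after filterByExpr, with TMM scaling, a trended dispersion, glmQLFit and the quasi-likelihood F test. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and rose, fell, higher and lower are used of called genes. All groups of a tissue share 1 estimate of the spread, so the single library of a group is assumed to vary like the others. The main comparison of a tissue was 1x minus control of the same week, averaged over the weeks that had both. Each week and each number of applications was also compared with its own control, 2x with 1x at week 9, 3x with 1x at week 12, and the last with the first control week. A model over all 3 tissues tested whether the averaged 1x effect differed between tissues. It gives each gene 1 spread for all tissues, so p-values between the meristems can be too small where flesh varies less. Genes tested numbered 24727 in primary meristem, 25648 in secondary meristem, 21557 in flesh and 26695 in the joint model. Levels of single genes are counts per 1e6 counts (CPM) with TMM scaling.

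Gene lists were fixed as word searches of the annotation, and those with at least 5 measured members were tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01. Camera asks whether a list moved more than the other genes, and its adjusted p runs over the lists tested. The same test with a correlation estimated from the residuals is given beside it. A further 15 lists were added after annotation wording and total numbers of calls had been seen, and are named as added. No list call in primary meristem held with the estimated correlation, and 1 each held in secondary meristem and flesh, both named where they occur.

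Single genes were named by a rule. For each averaged 1x, each 3x against 1x and each control storage comparison, these were the 5 with the largest positive and the 5 with the largest negative log2 change among called genes with a mean of at least 5 CPM and an informative description. That mean was taken over all libraries of the tissue, so a named gene can lie below it in the groups compared. In averaged comparisons the sign also had to be the same in every week. To these were added, for each list described, the member with the smallest p in each direction. The models, comparisons, lists, naming rule and most alternatives were chosen before the data were examined. Genes chosen otherwise are said to be so where named.

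The fitting steps were tested on simulated counts with 200 changed genes, 100 per fold size. For the averaged 1x comparison they recovered 60% of 2-fold and 90% of 4-fold changes in primary meristem, 50% and 80% in secondary meristem, and 91% and 99% in flesh. For 3 libraries against 3 at week 12, recovery was 14% and 74%, 17% and 69%, and 79% and 93%. For the difference between primary meristem and flesh 34% and 75% were recovered, and between the meristems 26% and 66%. Of the calls in the averaged comparisons 2.6%, 3% and 5.9% were false in primary meristem, secondary meristem and flesh, and 8.4% and 7.1% in the differences between tissues. In flesh DESeq2 recovered 92% and 100%, and 19.3% of its calls were false. A 2-fold change in a meristem at 1 week was thus mostly not detectable in the simulated counts. These had a single mean per gene over all groups and a spread from the trended dispersion. They held no week effects, no spread particular to a gene and no library unlike its group. The changed genes were drawn only from those above the lowest quartile of mean level, so recovery among weaker genes was not measured. Recovery and shares of false calls can therefore differ in the real data.

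Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, models on only the libraries compared, replicate number as a block, counts summed from the transcript table, and each library left out in turn. Chosen after seeing the data were the use of all 97 columns, of the transcript table outside the averaged comparisons, and of weeks 9 and 12 only in secondary meristem. So was the removal of 3 libraries that stood apart: primary meristem week 12 1x replicate 2 and 2x replicate 3, and secondary meristem week 9 2x replicate 2.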

Results

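The 88 libraries comprised 33 of primary meristem in 12 groups, 23 of secondary meristem in 9 groups and 32 of flesh in 12 groups. Groups held 3 libraries, except 9 groups with 2 and secondary meristem at week 6 under 1x with 1. Primary meristem and flesh had untreated tubers at weeks 0, 3, 6, 9 and 12, and secondary meristem at weeks 6, 9 and 12. Total counts ran from 23.2 to 38.7 M in primary meristem, from 22.5 to 36.1 M in secondary meristem and from 22.8 to 44.8 M in flesh. Between 16461 and 23241 genes were detected per library. The series asks how single and repeated DMN changes gene expression in each tissue during storage. The plot of called genes gives the size of each response against the control of the same week.

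**Figure D1:**
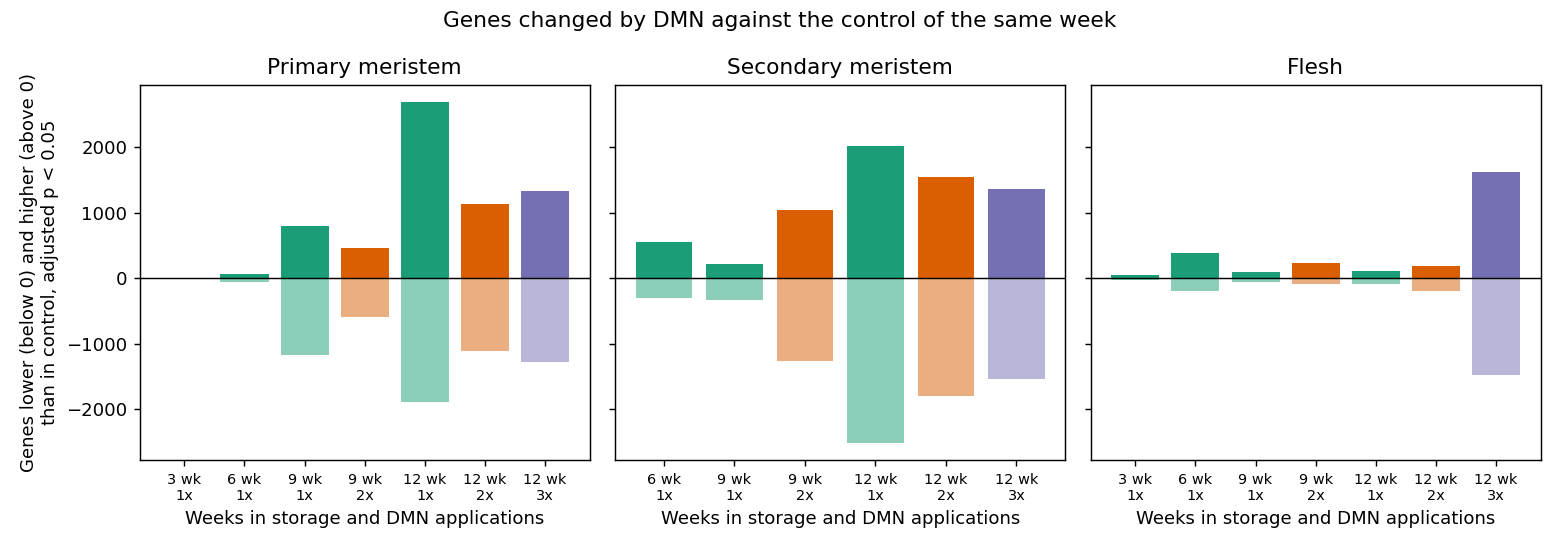
Number of genes called higher and lower (edgeR, adjusted p under 0.05) under DMN than in the control of the same week, per tissue, week and number of applications. In primary meristem 13 genes were called under 1x at week 3 and 4584 at week 12, and in flesh at week 12 it was 199 genes under 1x and 3097 under 3x.

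In untreated primary meristem 1911 genes rose and 1227 fell from week 0 (n = 2) to week 12 (n = 3). Of the 31 lists fixed before the data were examined, camera called 10 upward, among them core histones and DNA replication, and 2 downward, photosynthesis and starch breakdown. With an estimated correlation it called 0 of the 31. Of 62 core histone genes, 40 rose and 0 fell (48 and 1 adjusted over the list alone; camera adjusted p = 1.8e-15, and adjusted p = 0.23 with an estimated correlation). The summed histone level went from 1550 ± 211 CPM (SD, n = 2) to 6230 ± 1860 CPM (SD, n = 3), as in the plot of core histones per library. The 70 tuber storage and protease inhibitor genes, markers of flesh, summed to 668 ± 180 CPM (SD, n = 2) at week 0, 4590 ± 509 CPM (SD, n = 2) at week 3 and 2430 ± 1050 CPM (SD, n = 3) at week 12. From week 0 to week 12, 14 of them rose and 3 fell (17 and 3 adjusted over the list alone; camera adjusted p = 0.064). The histone gene called with the smallest p, Soltu_DM_11G004830, had a log2 fold change of 3.55 ± 0.53 (SE; edgeR adjusted p = 5.6e-05). Of 31 DNA replication genes 13 rose (15 adjusted over the list alone), led by MCM2/3/5 Soltu_DM_02G013800 at 4.21 ± 0.79 (SE; adjusted p = 0.00069). The list test gave adjusted p = 1.4e-05, and adjusted p = 0.23 with an estimated correlation. Of 10 genes for cyclins and mitosis 4 rose (7 adjusted over the list alone). Among them Aurora kinase Soltu_DM_12G004490, listed at 0 at week 0, reached 14.9 ± 3.82 CPM (SD, n = 3). Of 45 cell wall loosening genes 11 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 8.2e-04, and adjusted p = 0.41 with an estimated correlation). Expansin A4 (Soltu_DM_06G004100) went from 7.32 ± 0.907 CPM (SD, n = 2) to 97.6 ± 29.8 CPM (SD, n = 3). Of 14 gibberellin perception and response genes 4 rose (5 adjusted over the list alone), with Gibberellin-regulated protein Soltu_DM_03G030180 called with the smallest p (adjusted p = 0.00032). Of 18 suberin and periderm genes 7 rose (9 adjusted over the list alone), led by 3-ketoacyl-CoA synthase Soltu_DM_08G015830 at log2 3.75 ± 0.62 (SE). Of 48 vascular marker genes 8 rose and 1 fell (10 and 1 adjusted over the list alone). Sieve element occlusion gene Soltu_DM_03G025190, listed at 0 at week 0, reached 49.1 ± 18.8 CPM (SD, n = 3). Among the genes with the largest changes, sucrose synthase Soltu_DM_07G013360, lipid transfer protein Soltu_DM_10G018680, aldehyde dehydrogenase 2B7 (Soltu_DM_08G017320), an extensin family gene (Soltu_DM_02G017520) and a Fruit-specific protein (Soltu_DM_01G022210) were listed at 0 at week 0. Their means at week 12 ran from 53.5 to 83.6 CPM. A TCP factor of the branching list (Soltu_DM_03G030410) rose by a log2 fold change of 3.51 ± 0.47 (SE; adjusted p = 1.4e-05). Leaving out 1 library gave between 1059 calls, without week 0 replicate 2, and 2845, without week 12 replicate 1.

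The genes that fell in untreated primary meristem were led by glycosyl hydrolase 9B13 (Soltu_DM_08G030090), at a log2 fold change of −7.58 ± 0.91 (SE; adjusted p = 2.9e-06). ACC oxidase Soltu_DM_07G011040 had −5.53 ± 0.60 (SE; adjusted p = 7.3e-07), gibberellin 2-oxidase Soltu_DM_02G019740 had −5.13 ± 0.98 (SE; adjusted p = 0.00083) and ABA receptor PYR1-like Soltu_DM_09G009100 had −3.18 ± 0.52 (SE; adjusted p = 0.00014). Also among the largest falls were a pyruvate decarboxylase (Soltu_DM_10G019450, −7.37), a pair of HXXXD-type acyl-transferases (Soltu_DM_05G022700, −7.18, and Soltu_DM_05G022670, −6.44) and a Subtilase (Soltu_DM_08G026500, −6.42). Of 87 photosynthesis genes 13 fell and 0 rose (13 and 1 adjusted over the list alone; camera adjusted p = 1.2e-05, and adjusted p = 0.26 with an estimated correlation). Of 16 starch breakdown genes 4 fell and 1 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.015, and adjusted p = 0.26 with an estimated correlation), with alpha-amylase-like Soltu_DM_05G006330 at −3.07 ± 0.42 (SE).

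In primary meristem under 1x DMN, averaged over weeks 3, 6, 9 and 12 (n = 11 in each arm), 325 genes were higher and 219 lower than in controls. By week, 13 genes were called at week 3, 127 at week 6, 1967 at week 9 and 4584 at week 12 (2692 higher, 1892 lower). With RLE size factors the share of calls that were higher went from 59.7% to 50.6% on average and from 58.7% to 49.2% at week 12. With 1 library left out the counts ran from 27 to 69 at week 6, 184 to 2219 at week 9 and 1143 to 4467 at week 12. Fitted on only the compared libraries they were 6, 1158, 2581 and 1106, so the order of the weeks is not stable. Heat shock protein 70B (Soltu_DM_03G031860) was higher, at a log2 fold change of 1.45 ± 0.21 (SE; adjusted p = 0.0015). It went from 31.3 ± 6.38 to 149.0 ± 15.0 CPM at week 9 and from 29.3 ± 11.4 to 73.6 ± 25.3 CPM at week 12 (SD, n = 3 each). An Actin cross-linking protein (Soltu_DM_01G008360, 1.67), a Heavy metal transport protein (Soltu_DM_07G022200, 1.47), an extra-large G-protein (Soltu_DM_01G048750, 1.46) and a Nodulin MtN3 protein (Soltu_DM_03G020070, 1.43) were also higher, each with the same sign in all 4 weeks. Lower on average were a pair of aspartyl proteases (Soltu_DM_04G004760, −1.73, and Soltu_DM_05G002520, −1.40) and glycosyl hydrolase 9B13 (Soltu_DM_08G030090, −1.59). A Pectin lyase-like gene (Soltu_DM_08G028230, −1.53) and a Myzus persicae-induced lipase (Soltu_DM_02G010770, −1.29) were also lower. Each of these lower genes had the same sign in all 4 weeks, though a call in each week was not required. Gibberellin 2-oxidase Soltu_DM_02G019740, of the gibberellin breakdown list, was higher at 1.57 ± 0.42 (SE; adjusted p = 0.042), with weekly values from −0.36 at week 3 to 3.72 at week 12. Gibberellin-regulated Soltu_DM_03G027810 was lower at −1.12 ± 0.29 (SE; adjusted p = 0.039), at 49.7 ± 15.2 CPM against 483.0 ± 162.0 CPM in controls at week 12 (SD, n = 3 each). Expansin A4 (Soltu_DM_06G004100) was lower at −1.11 ± 0.23 (SE; adjusted p = 0.013), with 25.9 ± 11.9 against 97.6 ± 29.8 CPM at week 12 (SD, n = 3 each). An Auxin efflux carrier (Soltu_DM_04G038090, −0.93) and DNA polymerase epsilon subunit B2 (Soltu_DM_03G019150, −1.14) were lower. Cyclin-dependent kinase inhibitor Soltu_DM_12G002820 (0.79), alpha-amylase-like Soltu_DM_05G006330 (0.72), P450 71B gene Soltu_DM_08G020030 (1.15) and UDP-glycosyltransferase Soltu_DM_07G013870 (0.84) were higher. With each of the 22 libraries left out in turn, the alpha-amylase-like and Pectin lyase-like genes lost their call in 18 cases, gibberellin 2-oxidase in 15, P450 71B in 14, gibberellin-regulated Soltu_DM_03G027810 in 13 and the lipase in 11. Soltu_DM_05G006330 also lost it with RLE size factors and with no filter on low counts (log2 0.49 to 0.80 over all alternatives). Of 62 core histone genes 1 was higher and 1 lower on average (1 and 3 adjusted over the list alone; camera adjusted p = 1.7e-04, downward, and adjusted p = 0.88 with an estimated correlation). Of 56 pathogenesis-related genes 0 were higher and 2 lower in edgeR (1 and 9 adjusted over the list alone; camera adjusted p = 0.00056, downward, and adjusted p = 0.88 with an estimated correlation). Leaving out 1 library gave between 86 calls, without the week 3 control replicate 1, and 976, without the week 12 control replicate 1.

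At week 12 (n = 3 each), the histone difference in primary meristem was large. Under 1x, 33 of 62 core histone genes were lower and 3 higher, with a median log2 change of −2.32 (43 and 3 adjusted over the list alone; camera adjusted p = 1.2e-15, and adjusted p = 0.48 with an estimated correlation). The summed level was 2240 ± 732 CPM under 1x, 3040 ± 1640 CPM under 2x and 3120 ± 602 CPM under 3x, against 6230 ± 1860 CPM in controls (SD, n = 3 each). All 9 treated libraries lay at or below 4920 CPM, under the lowest control at 5150 CPM. In the same groups the 70 tuber storage and protease inhibitor genes, markers of flesh, summed to 2180 ± 2160, 3810 ± 1480 and 5650 ± 1140 CPM, against 2430 ± 1050 CPM in controls (SD, n = 3 each). Under 3x 6 of the 70 were higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.13). Whether added flesh contributes to the histone levels under 2x and 3x was not tested, and under 1x it was tested only as the whole cause. Under 2x and 3x, 11 histone genes each were lower and 1 higher (15 and 2, and 19 and 3, adjusted over the list alone). Of 14 gibberellin response genes 5 were lower under 1x and 0 higher in edgeR (5 and 0 adjusted over the list alone; camera adjusted p = 1.4e-05, and adjusted p = 0.48 with an estimated correlation). Of 31 DNA replication genes 8 were lower and 2 higher (9 and 2 adjusted over the list alone), of 45 cell wall loosening genes 7 lower (6 adjusted over the list alone), and of 56 pathogenesis-related genes 10 lower (10 adjusted over the list alone). Of 348 ribosomal protein genes, an added list, 158 were lower and 5 higher (camera adjusted p = 5.9e-21, and adjusted p = 0.57 with an estimated correlation). Of 87 photosynthesis genes 19 were higher and 1 lower under 3x (23 and 1 adjusted over the list alone; camera adjusted p = 2.7e-07, and adjusted p = 0.47 with an estimated correlation). In total 2242 genes were called under 2x (1134 higher, 1108 lower) and 2603 under 3x (1329 higher, 1274 lower). RLE size factors moved the share that was higher under 3x from 51.1% to 41.1%. At week 9, 2x against control called 459 genes higher and 594 lower (43.6% higher, and 53.3% with RLE size factors). The 2x and 1x groups of week 9 differed in 0 genes in edgeR and 98 genes in DESeq2. In edgeR 1200 of 24727 genes had an unadjusted p under 0.05, no larger a share than would be met without any difference. Fitted on the 6 compared libraries alone, edgeR called 0 genes under 2x, 1106 under 1x and 4569 under 3x. Leaving out 1 library gave 1143 to 4467 calls under 1x, 222 to 5085 under 2x and 1083 to 2848 under 3x. The lowest came without control replicate 2, 2x replicate 2 and 3x replicate 3, and the highest without 1x replicate 1, 2x replicate 3 and control replicate 1.

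**Figure D2:**
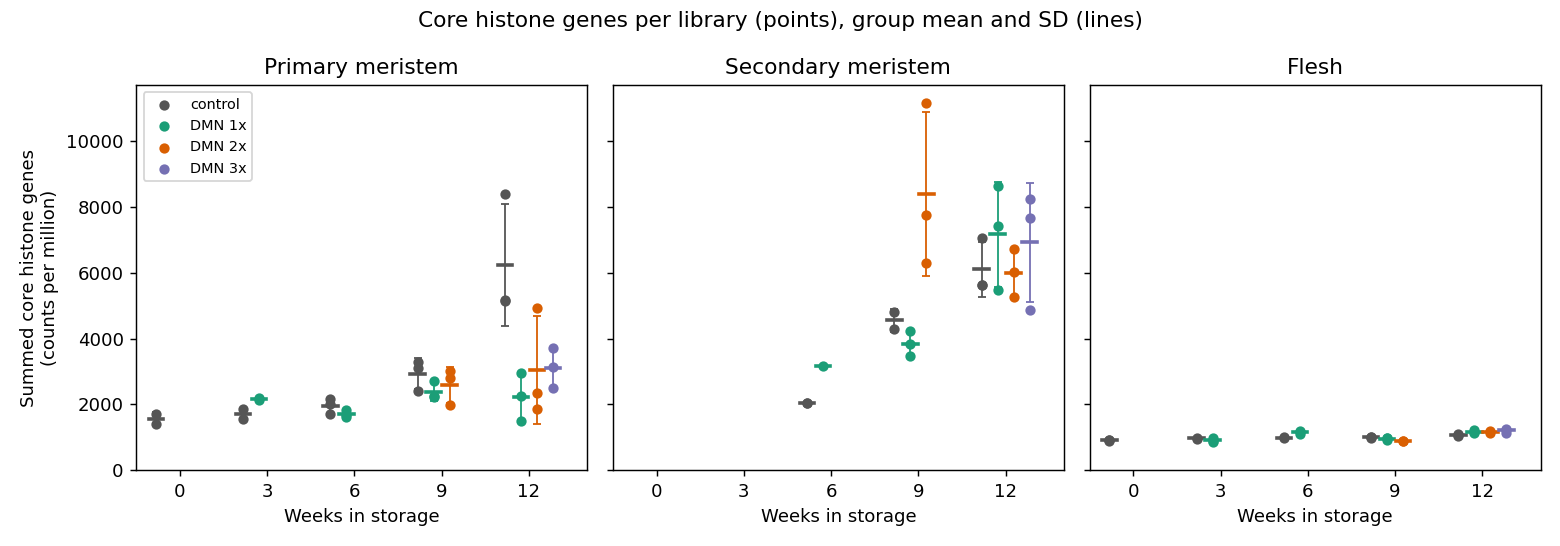
Summed level of the core histone genes (CPM) in each library, by tissue, week and number of DMN applications; points are libraries and lines are group means with SD. At week 12 the controls of primary meristem averaged 6230 CPM and the 1x libraries 2240 CPM, while secondary meristem averaged 6100 and 7170 CPM.

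In untreated secondary meristem 3300 genes rose and 1133 fell between week 6 (n = 2) and week 12 (n = 3). Of the 32 lists fixed before the data were examined, camera called 7 upward and 0 downward, and with an estimated correlation 0 of the 32. Whether this storage change differs from that of primary meristem was not tested. Of 62 core histone genes 45 rose and 0 fell (49 and 0 adjusted over the list alone; camera adjusted p = 4.5e-20, and adjusted p = 0.27 with an estimated correlation), led by Soltu_DM_01G028130 at a log2 fold change of 4.61 ± 0.31 (SE; edgeR adjusted p = 5.4e-09). Of 14 gibberellin response genes 9 rose (11 adjusted over the list alone), led by Soltu_DM_03G030180 at 5.08 ± 0.40 (SE; adjusted p = 1.9e-08). Of 50 cell wall loosening genes 21 rose and 1 fell (23 and 2 adjusted over the list alone), with expansin A4 (Soltu_DM_06G004100) at 2.57 ± 0.25 (SE; adjusted p = 1.7e-07). Of 22 genes for auxin synthesis and transport 11 rose (11 adjusted over the list alone), led by the efflux carrier Soltu_DM_10G026500 at 2.71 ± 0.27 (SE). Of 18 suberin and periderm genes 10 rose (12 adjusted over the list alone), led by 3-ketoacyl-CoA synthase Soltu_DM_10G005260 at 4.91 ± 0.83 (SE). A HAD superfamily phosphatase (Soltu_DM_06G022960), an Ethylene-responsive proteinase inhibitor (Soltu_DM_09G025890) and a Peroxidase (Soltu_DM_05G018820) were listed at 0 at week 6 and averaged 42.7 CPM or more at week 12. A NAD(P)-linked oxidoreductase (Soltu_DM_09G030800, −5.76) and an LRR kinase (Soltu_DM_10G006290, −5.73) led the genes that fell. Of the 4433 calls 1143 had a 0 in a compared library, and leaving out 1 library gave between 2646 calls, without week 6 replicate 3, and 3980, without week 12 replicate 1.

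In secondary meristem under 1x DMN, averaged over weeks 6, 9 and 12, 960 genes were higher and 1269 lower. The share that was higher went from 43.1% to 51.6% with RLE size factors, so the direction with more calls depends on the scaling. By week, 864 genes were called at week 6 (n = 1 against 2), 551 at week 9 (n = 3 against 2) and 4535 at week 12 (n = 3 each; 2018 higher, 2517 lower). Of the 864, 435 had a 0 in a compared library, and the 1 treated library of week 6 gives no spread of its own while week 6 weighs as much in the average as the other weeks. The count of week 9 was 0 in edgeR without control replicate 2. Allene oxide synthase Soltu_DM_10G003720 was higher at a log2 fold change of 2.15 ± 0.53 (SE; adjusted p = 0.016), at 24.3 ± 6.67 CPM (SD, n = 3) against 3.83 ± 1.06 CPM (SD, n = 2) at week 9. Ent-kaurenoic acid hydroxylase Soltu_DM_12G024040, of gibberellin synthesis, was higher at 1.63 ± 0.33 (SE; adjusted p = 0.0063), with 191.0 ± 92.5 against 27.5 ± 5.73 CPM at week 12 (SD, n = 3 each). Glutathione S-transferase Soltu_DM_12G008090 was higher at 0.77 ± 0.21 (SE; adjusted p = 0.025), with 106.0 ± 14.8 against 30.0 ± 0.594 CPM at week 12 (SD, n = 3 each). Starch synthase Soltu_DM_02G020170 was lower at −0.76 ± 0.14 (SE; adjusted p = 0.0043), with 105.0 ± 6.98 against 182.0 ± 6.63 CPM at week 12 (SD, n = 3 each). Among the genes with the largest averaged changes, an acid phosphatase (Soltu_DM_09G027280), an ethylene-forming enzyme (Soltu_DM_07G016780), a 2-oxoglutarate oxygenase (Soltu_DM_01G002170) and a pair of xyloglucan endotransglucosylases (Soltu_DM_09G030000 and Soltu_DM_12G028730) were listed at 0 in the week 6 controls. At week 12 they were at 32.7, 20.5, 29.9, 11.3 and 16.7 CPM under 1x, against 1.28, 3.37, 2.92, 2.54 and 3.08 CPM in controls. A phragmoplast orienting kinesin (Soltu_DM_01G048230), an IQ-domain gene (Soltu_DM_04G019410), an RCC1 family gene (Soltu_DM_02G020760), a B3 factor (Soltu_DM_08G002360) and a timeless gene (Soltu_DM_03G023110) were lower and listed at 0 in that treated library. With weeks 9 and 12 only, the kinesin and the 5 higher genes stayed called, and the 4 last were no longer called (adjusted p = 0.55, 0.94, 0.26 and 0.81, within 1.5e-05 to 0.94 over all alternatives of the 4). Of 71 glutathione transferase genes 5 were higher and 0 lower (3 and 0 adjusted over the list alone; camera adjusted p = 0.00066, and adjusted p = 0.40 with an estimated correlation). Of 62 core histone genes 12 were higher and 0 lower in edgeR (12 and 0 adjusted over the list alone; camera adjusted p = 0.0023, and adjusted p = 0.49 with an estimated correlation). At week 9 the histone list moved downward (camera adjusted p = 0.033, and adjusted p = 0.95 with an estimated correlation), at 3850 ± 377 CPM (SD, n = 3) against 4550 ± 363 CPM (SD, n = 2). In all 12 of 32 lists were called upward, and 0 of them with the estimated correlation. The averaged count was 2229, and 3951 with weeks 9 and 12 only. Leaving out 1 library gave between 1189 calls, without the week 9 control replicate 1, and 2070, without the week 9 1x replicate 2.

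At week 12 in secondary meristem (n = 3 each), 1x, 2x and 3x called 4535, 3340 and 2900 genes. With 1 library left out the counts ran from 2604 to 3787, 1318 to 2978 and 499 to 3899, so their order is not stable. The lowest came without replicate 2 of the treated group each time, and the highest without 1x replicate 1, 2x replicate 3 and 3x replicate 3. Glutathione transferases were counted separately for each number of applications. Of 71 genes 15 were higher under 1x with 1 lower, 14 under 2x and 20 under 3x with 0 lower in edgeR. Adjusted over the list alone these were 18, 20 and 23. The camera adjusted p was 7.7e-05, 1.0e-05 and 2.3e-06, and adjusted p = 0.37, 0.44 and 0.48 with an estimated correlation. Of 50 cell wall loosening genes 10 were higher and 1 lower under 1x (11 and 1 adjusted over the list alone; camera adjusted p = 1.2e-04, and adjusted p = 0.37 with an estimated correlation). Of 62 core histone genes 17 were higher and 3 lower under 1x (18 and 3 adjusted over the list alone; camera adjusted p = 0.0036, and adjusted p = 0.66 with an estimated correlation). Of 17 starch breakdown genes 6 were lower and 1 higher under 1x (6 and 1 adjusted over the list alone; camera adjusted p = 0.019, and adjusted p = 0.37 with an estimated correlation). Of 73 tuber storage and protease inhibitor genes, which are markers of flesh, 13 were higher under 1x and 20 under 3x (13 and 24 adjusted over the list alone). Of 57 pathogenesis-related genes 11 were higher under 3x (12 adjusted over the list alone). Week 9 under 2x called 1045 genes higher and 1267 lower, and 888 higher and 313 lower against 1x. Without the library that stood apart in that group, the difference from 1x was 301 genes. With RLE size factors the median of all genes under 1x at week 12 lay 0.103 higher on the log2 scale, and the share of calls that were higher went from 44.5% to 54.6%. Under 2x it went from 46.4% to 57.4% and under 3x from 47.1% to 59.1%.

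In untreated flesh 4748 genes rose and 4943 fell from week 0 to week 12 (n = 3 each), and leaving out 1 library gave between 8828 and 8983 calls. Flesh libraries varied least (common dispersion 0.0717, against 0.435 in primary and 0.349 in secondary meristem), so numbers of calls do not rank the tissues. Of 9 ABA perception and signalling genes 2 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.86), and of 44 LEA and dehydrin genes 13 rose and 8 fell (13 and 8 adjusted over the list alone; camera adjusted p = 0.51). The dormancy-associated gene Soltu_DM_03G001970 rose at a log2 fold change of 3.51 ± 0.17 (SE; adjusted p = 2.2e-15), from 7.65 ± 0.627 to 87.1 ± 8.64 CPM (SD, n = 3 each). Highly ABA-induced PP2C Soltu_DM_06G031720 rose at 2.66 ± 0.12 (SE; adjusted p = 2.0e-16), a Dehydrin (Soltu_DM_02G024670) at 3.39 ± 0.32 (SE; adjusted p = 1.1e-09) and Cyclin-dependent kinase inhibitor Soltu_DM_12G002820 at 2.06 ± 0.08 (SE; adjusted p = 3.2e-17). The largest rises were in a Cysteine proteinase (Soltu_DM_03G025120, 6.76), a pair of nodulin MtN21-like transporters (Soltu_DM_05G007940, 6.26, and Soltu_DM_10G026390, 5.91), a TPR-like gene (Soltu_DM_06G023820, 5.35) and Walls Are Thin (Soltu_DM_04G036030, 5.17). ACC oxidase Soltu_DM_07G011040 fell at −4.43 ± 0.27 (SE; adjusted p = 1.7e-13), from 142.0 ± 24.3 to 6.57 ± 0.937 CPM (SD, n = 3 each). Alpha-amylase-like Soltu_DM_05G006330 fell from 369.0 ± 29.0 to 29.7 ± 2.34 CPM (SD, n = 3 each). Sucrose synthase Soltu_DM_07G013370 fell at −2.01 ± 0.07 (SE), while sucrose synthase Soltu_DM_02G020800 rose at 2.86 ± 0.35 (SE). A beta HLH protein (Soltu_DM_04G031540), a Serine protease inhibitor (Soltu_DM_08G027250), a subtilisin-like protease (Soltu_DM_01G026810), a Peroxidase (Soltu_DM_03G005520) and an amino acid transporter (Soltu_DM_05G002690) were at 23.8 to 40.9 CPM at week 0 and listed at 0 at week 12. Of 64 photosynthesis genes 31 fell and 2 rose (32 and 2 adjusted over the list alone; camera adjusted p = 0.010, and adjusted p = 0.69 with an estimated correlation), led by photosystem II subunit O-2 (Soltu_DM_02G008740) at −5.40 ± 0.36 (SE).

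In flesh under 1x DMN, most called genes were higher. Averaged over weeks 3, 6, 9 and 12 (n = 12 against 10), 371 genes were higher and 165 lower. By week, 79, 578, 152 and 199 genes were called at weeks 3, 6, 9 and 12. With 1 library left out the lowest counts were 0, 6, 34 and 32 in edgeR. An EF hand calcium-binding gene (Soltu_DM_02G026800) was higher at a log2 fold change of 1.56 ± 0.20 (SE; adjusted p = 1.2e-04) and at 1.28 or more in every week, for example 23.1 ± 2.16 CPM (SD, n = 3) against 6.46 ± 1.33 CPM (SD, n = 2) at week 6. A SOS3-interacting protein (Soltu_DM_06G032750, 1.64), a DDE endonuclease domain gene (Soltu_DM_12G025950, 1.65), an LEA gene (Soltu_DM_01G034240, 1.56) and cellulose synthase-like D3 (Soltu_DM_03G020780) were higher. Each had the same sign in all 4 weeks, though a call in each week was not required. Cellulose synthase-like D3 went from 12.5 ± 4.69 CPM (SD, n = 2) to 76.1 ± 16.5 CPM (SD, n = 3) at week 6. It was listed at 0 in the week 12 controls. A further LEA gene (Soltu_DM_01G034250) was higher at 0.70 ± 0.08 (SE; adjusted p = 2.9e-05). An HXXXD-type acyl-transferase (Soltu_DM_09G000540) was lower at −0.68 ± 0.07 (SE; adjusted p = 3.2e-06), and at week 12 had 33.3 ± 6.77 against 117.0 ± 3.37 CPM (SD, n = 3 each). Another SOS3-interacting protein (Soltu_DM_06G010880, −0.55), MCM2/3/5 Soltu_DM_02G013800 (−0.55), a Peroxidase (Soltu_DM_08G018410, −0.51) and a homeobox gene (Soltu_DM_04G001110, −0.49) were lower. Their sign was also the same in all 4 weeks. With each of the 22 libraries left out in turn, MCM2/3/5 Soltu_DM_02G013800 lost its call in 17 cases, the Peroxidase in 15 and the LEA gene Soltu_DM_01G034240 in 13. A beta-amylase (Soltu_DM_09G027770, 0.56), glutathione S-transferase Soltu_DM_07G022470 (0.40), P450 71B gene Soltu_DM_08G020030 (0.44) and UDP-glycosyltransferase Soltu_DM_07G013870 (0.30) were higher. Of 31 DNA replication genes 1 was lower (1 adjusted over the list alone; camera adjusted p = 0.046, and adjusted p = 0.20 with an estimated correlation), the only 1 of 27 lists called. Of 50 WRKY factor genes, an added list, 4 were higher and 0 lower (camera adjusted p = 0.0040, and adjusted p = 0.0071 with an estimated correlation). Leaving out 1 library gave between 249 calls, without the week 6 control replicate 3, and 735, without the week 12 1x replicate 3.

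The flesh response at week 12 was largest under 3x, with 1626 genes higher and 1471 lower than in controls (n = 3 each), against 119 and 80 under 1x (n = 3) and 196 and 185 under 2x (n = 2). Against 1x, 3x had 1018 genes higher and 1173 lower. Cysteine synthase C1 (Soltu_DM_10G006300) went from 5.83 ± 0.634 CPM under 1x to 39.9 ± 1.95 CPM under 3x (SD, n = 3 each; adjusted p = 2.8e-14). Basic chitinase Soltu_DM_10G017910 was higher at a log2 fold change of 4.94 ± 0.63 (SE; adjusted p = 5.3e-06), osmotin Soltu_DM_08G027270 at 3.09 ± 0.52 (SE; adjusted p = 1.8e-04) and PHE ammonia lyase Soltu_DM_09G005690 at 2.71 ± 0.44 (SE; adjusted p = 1.0e-04). MCM2/3/5 Soltu_DM_02G013800 was higher at 1.93 ± 0.30 (SE; adjusted p = 6.6e-05), at 11.7 ± 2.65 CPM against 3.08 ± 0.504 CPM under 1x and 5.37 ± 2.06 CPM in controls (SD, n = 3 each). The dormancy-associated gene Soltu_DM_03G001970 was lower at −0.98 ± 0.15 (SE; adjusted p = 6.7e-05), at 54.8 ± 13.6 CPM against 108.0 ± 11.5 CPM under 1x (SD, n = 3 each). PP2C Soltu_DM_03G022710 (−1.18), a Dehydrin (Soltu_DM_02G024670), an ethylene-responsive element binding protein (Soltu_DM_01G020840, −1.63) and UDP-glycosyltransferase Soltu_DM_03G012270 (−1.35) were lower. Subtilase 1 (Soltu_DM_03G016270, −2.65), UDP-glucosyl transferase 85A5 (Soltu_DM_03G012220, −2.53) and an ethylene response factor (Soltu_DM_09G021200, −2.34) had large falls. Nitrate transporter 1 (Soltu_DM_08G025260, 0.675 CPM under 1x) and a polygalacturonase (Soltu_DM_06G028510, 0.625 CPM under 1x) were listed at 0 under 3x. A dehydroquinate dehydratase (Soltu_DM_10G008120, 0.771 CPM under 3x) was listed at 0 under 1x. Of 64 photosynthesis genes 13 were higher and 0 lower in edgeR (21 and 0 adjusted over the list alone; camera adjusted p = 4.8e-07, and adjusted p = 0.49 with an estimated correlation), led by photosystem II subunit X (Soltu_DM_05G015670, 1.13). Against control, 23 of the 64 were higher under 3x and 0 lower (27 and 1 adjusted over the list alone; camera adjusted p = 4.5e-07, and adjusted p = 0.27 with an estimated correlation). Of 340 ribosomal protein genes, an added list, 147 were higher and 11 lower than in controls (camera adjusted p = 3.2e-19, and adjusted p = 0.34 with an estimated correlation). Of 58 core histone genes 11 were higher and 3 lower than in controls (12 and 3 adjusted over the list alone; camera adjusted p = 0.006, and adjusted p = 0.083 with an estimated correlation). Of 20 shoot meristem and leaf primordium markers 4 were higher and 0 lower in edgeR (6 and 0 adjusted over the list alone; camera adjusted p = 0.027, and adjusted p = 0.083 with an estimated correlation). Of 51 tuber storage and protease inhibitor genes 15 were higher and 2 lower (16 and 3 adjusted over the list alone; camera adjusted p = 0.009, and adjusted p = 0.45 with an estimated correlation). Of 49 glutathione transferase genes 10 were higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 0.009, and adjusted p = 0.16 with an estimated correlation). Leaving out 1 library gave between 2140 and 3218 calls against control and between 1531 and 2112 against 1x.

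At week 12 a few genes annotated as P450, glycosyltransferase and hydroxycinnamoyl transferase were higher under 3x than under 1x in both meristems. As lists, P450, UDP-glycosyltransferase and phenylpropanoid genes moved upward in primary meristem (camera adjusted p = 0.022, 0.0097 and 0.025, and adjusted p = 0.42, 0.42 and 0.44 with an estimated correlation). They were not called in secondary meristem (camera adjusted p = 0.43, 0.72 and 0.29). P450 76G gene Soltu_DM_10G024690 was called in all 3 tissues, at a log2 fold change of 2.44 ± 0.31 (SE; adjusted p = 0.00021) in primary meristem, 2.26 ± 0.30 (SE; adjusted p = 0.0021) in secondary meristem and 1.17 ± 0.09 (SE; adjusted p = 9.2e-09) in flesh. In primary meristem it averaged 24.6 CPM in controls, 44.2 under 1x, 99.6 under 2x and 240.0 under 3x, and in secondary meristem 22.5, 59.6, 86.6 and 286.0 CPM (n = 3 each). Groups with more applications may also have had a more recent one, so number and timing cannot be told apart here. UDP-glycosyltransferase 73B4 (Soltu_DM_10G028080) was higher at 1.65 ± 0.33 (SE; adjusted p = 0.033) in primary and 2.48 ± 0.38 (SE; adjusted p = 0.0083) in secondary meristem. Hydroxycinnamoyl transferase Soltu_DM_07G000810 was higher at 1.33 ± 0.20 (SE; adjusted p = 0.0015) and 1.35 ± 0.21 (SE; adjusted p = 0.0083), at 476.0 ± 62.9 and 510.0 ± 99.8 CPM under 3x (SD, n = 3 each). P450 71B gene Soltu_DM_06G018970 was higher at 2.66 ± 0.45 (SE; adjusted p = 0.0088) and 2.68 ± 0.44 (SE; adjusted p = 0.0097). Primary meristem called 124 genes higher and 711 lower, and secondary meristem 22 higher and 0 lower in edgeR (1845 at an unadjusted p under 0.05). In primary meristem a CAP protein (Soltu_DM_01G045970, 2.13), Kunitz inhibitor Soltu_DM_03G018450 (3.04), a PLAT/LH2 lipase (Soltu_DM_03G012640, 2.98), an MLP-like protein (Soltu_DM_09G027720, 2.94), glutathione S-transferase zeta (Soltu_DM_01G041440, 1.22) and photosystem I subunit E-2 (Soltu_DM_09G018670, 1.30) were higher. The auxin transport protein BIG (Soltu_DM_02G030530, −3.76), an actin binding gene (Soltu_DM_06G025740, −5.22), an embryo defective gene (Soltu_DM_03G023770, −4.78), a DNAJ gene (Soltu_DM_08G009790, −3.85) and a calcium-dependent lipid-binding gene (Soltu_DM_09G003800, −3.62) were lower. In secondary meristem a pleiotropic drug resistance transporter (Soltu_DM_09G028720), listed at 0 under 1x, reached 43.5 ± 30.6 CPM under 3x (SD, n = 3). A Galactose oxidase/kelch gene (Soltu_DM_03G034960, 2.97), an LRR kinase (Soltu_DM_03G025180, 2.87) and a Rossmann-fold gene (Soltu_DM_04G010630, 2.62) were also higher there. Of 85 photosynthesis genes 1 was higher in secondary meristem (15 adjusted over the list alone; camera adjusted p = 6.8e-10, and adjusted p = 0.046 with an estimated correlation), chlorophyll A/B binding protein Soltu_DM_02G014000 at 1.84 ± 0.33 (SE). Without the library of the 1x group that stood apart and that of the 2x group, primary meristem called 5 genes, and with a fit on only the libraries compared 0 in edgeR. The genes named as lower in primary meristem, and there also Soltu_DM_03G018450, Soltu_DM_03G012640, Soltu_DM_09G027720, Soltu_DM_01G041440, Soltu_DM_09G018670 and Soltu_DM_10G028080, lost their call in 4 of 6 cases with 1 library left out. In secondary meristem Soltu_DM_02G014000 lost it in 5 of 6, Soltu_DM_06G018970 and Soltu_DM_04G010630 in 4, and Soltu_DM_07G000810, Soltu_DM_10G028080 and Soltu_DM_09G028720 in 3. In primary meristem Soltu_DM_06G018970 lost it in 2 and without the libraries that stood apart. Soltu_DM_02G014000 also lost its call with only the compared libraries and with the summed transcript table. In primary meristem the count of 835 was 2019 without 1x replicate 1, 4 without 1x replicate 2, 1670 without 1x replicate 3, and 7, 6 and 10 without 3x replicates 1, 2 and 3. In secondary meristem it ran from 4, without 1x replicate 3, to 27, without 3x replicate 2.

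The averaged 1x effect differed between tissues when the difference itself was tested. Between primary meristem and flesh 46 genes had a higher and 115 a lower effect in primary meristem, and between primary and secondary meristem 1723 and 1542. With RLE size factors the share higher against flesh went from 28.6% to 42.9%. A lower effect here is a more negative log2 change, which can be a stronger fall. The joint model shares its estimate of the spread over tissues, although flesh varied less (common dispersion 0.0717, against 0.435 in primary and 0.349 in secondary meristem). Its p-values for the difference between the meristems can thus be too small. For that difference replicate number 2 could not be left out, because the week 6 1x group of secondary meristem would be empty. Leaving out all samples of 1 replicate number brought the 161 genes to between 4, without replicate 1, and 49, without replicate 3, and the 3265 to between 695 and 3052, without the same numbers. Heat shock protein 70B (Soltu_DM_03G031860) responded more in primary meristem than in flesh, by 1.35 ± 0.27 (SE) on the log2 scale (adjusted p = 0.013). An Auxin efflux carrier (Soltu_DM_04G038090), lower under 1x in primary meristem, had an effect there below that in flesh, by −0.85 ± 0.21 (SE; adjusted p = 0.036), and below that in secondary meristem, by −0.83 ± 0.25 (SE; adjusted p = 0.019). Histone H2A Soltu_DM_11G026750 differed by −0.90 ± 0.23 (SE; adjusted p = 0.042) and −1.16 ± 0.27 (SE; adjusted p = 0.0030). Between the meristems, abscisic aldehyde oxidase Soltu_DM_11G024430 (0.76), an Aurora kinase (Soltu_DM_04G020860, 0.74) and alpha-amylase-like Soltu_DM_05G006330 had a higher effect in primary meristem. Gibberellin-regulated Soltu_DM_03G027810 (−1.51), a Chlorophyll A-B binding gene (Soltu_DM_08G001070, −1.03) and glutathione S-transferase THETA (Soltu_DM_12G008090, −1.49) had a lower effect there. Of 63 core histone genes 26 had a lower effect in primary than in secondary meristem and 0 a higher one in edgeR (camera adjusted p = 6.2e-10, and adjusted p = 0.33 with an estimated correlation). Of 71 glutathione transferase genes 10 had a lower effect and 0 a higher one.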

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

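All tests of explanations in this part were chosen only after the result was seen, except the thinning of flesh libraries to equal depth. Leaving out each library in turn had been planned as an alternative, but its use as a test of these explanations had not.

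What set these results apart is a tested difference between tissues in the averaged 1x effect. Between primary meristem and flesh 161 genes differed, and between the meristems 3265. The limit of a spread shared by all tissues applies to these counts and to the histone difference at week 12 below. The averaged difference between the meristems also rests in part on the single week 6 1x library of secondary meristem. Heat shock protein 70B (Soltu_DM_03G031860) responded more in primary meristem than in flesh, by 1.35 on the log2 scale. An aspartyl protease (Soltu_DM_05G002520), lower under 1x in primary meristem, had an effect there below that in secondary meristem, by −1.54 (SE 0.46; edgeR adjusted p = 0.022). The 2-oxoglutarate oxygenase Soltu_DM_01G002170 (−4.39), RCC1 family gene Soltu_DM_02G020760 (3.37) and B3 factor Soltu_DM_08G002360 (4.04) also differed between the meristems. Each was listed at 0 in a compared group of secondary meristem at week 6, so the size of these fitted differences is uncertain and they are not to be read as fold changes. With weeks 9 and 12 only, the last 2 were no longer called in secondary meristem. At week 12 alone, 46 of 63 core histone genes had a lower 1x response in primary than in secondary meristem and 3 a higher one, with a median difference of −3.04 (camera adjusted p = 3.2e-13, and adjusted p = 0.19 with an estimated correlation).

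The histone difference at week 12 could have come from the libraries that stood apart, or from more flesh in the treated primary meristem samples, since flesh has low histone levels. Without the libraries that stood apart, 42 of the 46 genes still had a lower response, so those libraries are not the whole cause. With CPM scaled over all 3 tissues together, which differ from the sums per tissue in the report, to lower the summed histone level from 6320 to 2090 CPM by mixing, with flesh at 1170 CPM, would take a share of 82.1% flesh in the treated samples. The 15 storage protein and protease inhibitor genes at least 4 times higher in flesh then lay far below the level this predicts, with a median log2 ratio of −3.17 and 0 of 15 reaching it. For example, Kunitz inhibitor Soltu_DM_03G023510 was at 5810 CPM in flesh, 471 in control and 536 in treated primary meristem, against 4860 predicted. These values argue against added flesh as the whole cause of the fall in the group mean under 1x. A smaller contribution, or added flesh in single libraries, was not tested. With CPM scaled per tissue, the summed flesh markers ran from 491 to 4610 CPM under 1x. In controls they ran from 1230 to 3100 CPM. A response to DMN that differs between the meristems remains possible. A difference in growth stage or in the share of dividing tissue sampled was not tested, nor was the share of flesh under 2x and 3x.

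In primary meristem at week 12, 3x against 1x called 835 genes, 711 of them lower, and a 1x library that stood apart could be the cause. Without that library (replicate 2) 4 genes were called, while the count rose without another 1x library, to 2019 without replicate 1. Without any 1 of the 3x libraries 6 to 10 genes were called. The 835 calls thus depend on that library, and also on each 3x library. Whether that library is the cause stays open. Its depth of 33.3 M counts lay within the 27.2 to 33.6 M of the other 5 libraries, which excludes depth. No measure of RNA quality was used here.

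In flesh at week 12, 3x called 3097 genes against control, and this could rest on 1 library or on depth. With 1 library left out the lowest count was 2140, and with every flesh library thinned to 22.8 M counts 3x called 3087 genes and 1x 199. Both explanations are excluded. The timing of the last application cannot be told apart from the number of applications. Whether more meristem tissue in the treated flesh samples matters was not tested.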

How the results depend on the processing

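The use of all 97 columns, of weeks 9 and 12 only, and of the libraries without those that stood apart was chosen only after the results had been seen, as was the transcript table outside the averaged comparisons. Below, each count of called genes is given as the main value and then the value under the alternative, where the change was over 1.5 times. The remaining counts stayed within 1.5 times.

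With RLE size factors and with no filter on low counts, 0 of 37 and 0 of 37 counts of calls changed by over 1.5 times, and 4 and 10 of 377 named-gene values lost their call. RLE moved the share of calls that were higher by at most 3.9 percentage points, except as follows. Shares in primary meristem average 59.7% to 50.6%, week 9 2x 43.6% to 53.3%, week 12 1x 58.7% to 49.2%, week 12 3x 51.1% to 41.1%. Shares in secondary meristem average 43.1% to 51.6%, week 9 1x 39.7% to 48.1%, week 12 1x 44.5% to 54.6%, week 12 2x 46.4% to 57.4%, week 12 3x 47.1% to 59.1%, storage 74.4% to 65.3%. Shares for the difference between primary meristem and flesh 28.6% to 42.9%.

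With DESeq2, 25 of 34 counts changed by over 1.5 times and 3 of 376 named-gene values lost their call. In primary meristem average 544 to 1785, week 3 1x 13 to 294, week 6 1x 127 to 810, week 9 1x 1967 to 3455, week 9 2x 1053 to 2395, week 12 2x 2242 to 3648, week 12 3x 2603 to 3981, week 9 2x against 1x 0 to 98, week 12 3x against 1x 835 to 2030, storage 3138 to 4963. In secondary meristem average 2229 to 3514, week 6 1x 864 to 1871, week 9 1x 551 to 1867, week 9 2x 2312 to 3935, week 9 2x against 1x 1201 to 2584, week 12 3x against 1x 22 to 141. In flesh average 536 to 1155, week 3 1x 79 to 482, week 6 1x 578 to 1407, week 9 1x 152 to 450, week 9 2x 323 to 607, week 12 1x 199 to 674, week 12 2x 381 to 1104, week 9 2x against 1x 27 to 112. For the difference between primary meristem and flesh 161 to 763. In simulated flesh counts 19.3% of DESeq2 calls were false, against 5.9% in edgeR, and the cause of the larger counts was not tested.

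With a fit on only the libraries of the groups compared, 23 of 32 counts changed by over 1.5 times and 48 of 371 named-gene values lost their call. In primary meristem average 544 to 1004, week 3 1x 13 to 6, week 6 1x 127 to 1158, week 9 2x 1053 to 362, week 12 1x 4584 to 1106, week 12 2x 2242 to 0, week 12 3x 2603 to 4569, week 12 3x against 1x 835 to 0. In secondary meristem average 2229 to 4505, week 6 1x 864 to 540, week 9 1x 551 to 1335, week 9 2x 2312 to 0, week 12 1x 4535 to 7042, week 9 2x against 1x 1201 to 0, week 12 3x against 1x 22 to 60. In flesh week 3 1x 79 to 0, week 6 1x 578 to 254, week 9 2x 323 to 182, week 12 1x 199 to 19, week 12 2x 381 to 58, week 12 3x 3097 to 1884, week 9 2x against 1x 27 to 2, week 12 3x against 1x 2191 to 918. Fewer libraries enter each of these fits, and beyond that the cause was not tested.

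With counts summed from the transcript table, 17 of 37 counts changed by over 1.5 times and 39 of 377 named-gene values lost their call. This setting takes in shallow libraries, among them secondary meristem libraries of week 6 with 472806 counts under 1x and 5336586 in a control. In primary meristem average 544 to 862, week 12 3x against 1x 835 to 529, lists 2 to 4. In secondary meristem average 2229 to 1055, week 6 1x 864 to 489, week 9 1x 551 to 44, week 9 2x 2312 to 731, week 12 1x 4535 to 2428, week 12 2x 3340 to 1444, week 12 3x 2900 to 1156, week 9 2x against 1x 1201 to 79, week 12 3x against 1x 22 to 13. In flesh week 3 1x 79 to 336, week 6 1x 578 to 1233, week 9 2x 323 to 702, week 9 2x against 1x 27 to 115, lists 1 to 0. The cause was not tested.

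With all 97 columns, 24 of 37 counts changed by over 1.5 times and 0 of 377 named-gene values lost their call. In primary meristem average 544 to 1847, week 3 1x 13 to 221, week 6 1x 127 to 348, week 9 1x 1967 to 3032, week 9 2x 1053 to 1836, week 12 3x against 1x 835 to 1282, storage 3138 to 5899. In secondary meristem average 2229 to 4849, week 6 1x 864 to 3724, week 9 1x 551 to 1212, week 9 2x against 1x 1201 to 1957, week 12 3x against 1x 22 to 44, storage 4433 to 6716. In flesh average 536 to 1488, week 3 1x 79 to 755, week 6 1x 578 to 2137, week 9 1x 152 to 399, week 9 2x 323 to 918, week 12 1x 199 to 559, week 12 2x 381 to 1975, week 9 2x against 1x 27 to 234, lists 1 to 0. For the difference between primary meristem and flesh 161 to 923, the difference between the meristems 3265 to 5549. The averaged columns lie between the libraries they average and so narrow the spread.

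With the 3 libraries that stood apart left out, 15 of 25 counts changed by over 1.5 times and 20 of 235 named-gene values lost their call. In primary meristem average 544 to 1590, week 3 1x 13 to 28, week 6 1x 127 to 685, week 9 1x 1967 to 3527, week 9 2x 1053 to 2423, week 12 2x 2242 to 5636, week 9 2x against 1x 0 to 3, week 12 3x against 1x 835 to 5, storage 3138 to 4784. In secondary meristem average 2229 to 3465, week 6 1x 864 to 1589, week 9 1x 551 to 1405, week 9 2x against 1x 1201 to 301, week 12 3x against 1x 22 to 35. For the difference between primary meristem and flesh 161 to 715. The cause was not tested.

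Groups share replicate numbers, and the labels state no pairing. With the replicate number as a replicate block, 4 of 37 counts changed by over 1.5 times and 41 of 377 named-gene values lost their call. In primary meristem week 12 3x against 1x 835 to 26. In flesh week 12 2x 381 to 244, lists 1 to 2. For the difference between primary meristem and flesh 161 to 102. Samples sharing a number correlated on average at −0.014, 0.022 and −0.002 in primary meristem, secondary meristem and flesh, with 44 of 165, 24 of 70 and 5 of 157 pairs above 0.1. Between tissues, samples of the same week, treatment and number correlated on average at −0.067 for primary and secondary meristem, 0.008 for primary meristem and flesh and 0.069 for secondary meristem and flesh, with 6 of 22, 4 of 29 and 9 of 20 pairs above 0.1, a check added after the results had been seen. Samples of other numbers correlated on average at 0.007, −0.011 and 0.001 within the tissues, in the same order. Between tissues these were 0.034, −0.004 and −0.036, again in the same order. Not every pair sharing a number lay above 0.1, and the samples were kept unpaired. With few libraries per group single pairs are noisy, so that rule cannot decide whether samples are paired. Shared tubers are not excluded. The cause of the changed counts was not tested.

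With an estimated correlation, camera called 0, 0, 0 of the lists fixed before the data were examined, on average over weeks in the 3 tissues, from 2, 12, 1. With weeks 9 and 12 only, the secondary meristem average went from 2229 to 3951 and the difference between the meristems from 3265 to 2426. There 20 of 46 named-gene values lost their call and 4 changed sign, at log2 changes of Soltu_DM_01G050410 −0.34, Soltu_DM_04G033700 0.07, Soltu_DM_06G009010 0.26, Soltu_DM_08G014220 −0.02. This setting drops the treated library and both controls of week 6, and the cause of these changes was not tested.

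Leaving out each library in turn kept the call of 2761 of 3391 named-gene values, and 629 lost it. The value for Soltu_DM_06G024540 in flesh under 3x against 1x became 0 without week 12 1x replicate 2 (lowest −7.01 and highest 0 over the libraries left out). The lowest and highest counts of calls were as follows. In primary meristem average 86 to 976, week 3 1x 16 to 39, week 6 1x 27 to 69, week 9 1x 184 to 2219, week 9 2x 96 to 1199, week 12 1x 1143 to 4467, week 12 2x 222 to 5085, week 12 3x 1083 to 2848, week 9 2x against 1x 0 to 26, week 12 3x against 1x 4 to 2019, storage 1059 to 2845. In secondary meristem average 1189 to 2070, week 6 1x 657 to 705, week 9 1x 0 to 475, week 9 2x 493 to 2989, week 12 1x 2604 to 3787, week 12 2x 1318 to 2978, week 12 3x 499 to 3899, week 9 2x against 1x 301 to 2560, week 12 3x against 1x 4 to 27, storage 2646 to 3980. In flesh average 249 to 735, week 3 1x 0 to 249, week 6 1x 6 to 474, week 9 1x 34 to 153, week 9 2x 116 to 280, week 12 1x 32 to 407, week 12 2x 146 to 420, week 12 3x 2140 to 3218, week 9 2x against 1x 8 to 26, week 12 3x against 1x 1531 to 2112, storage 8828 to 8983. For the difference between primary meristem and flesh 4 to 49, the difference between the meristems 695 to 3052. For the differences between tissues all samples with 1 replicate number were left out. The single week 6 1x library of secondary meristem was not left out, because its group would be empty. Where 1 library remained in a group it was assumed to vary like the others, and the cause of these ranges was not tested.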

Other observations

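The tests of overlap, the comparison with held-out controls and the lists named as added were chosen only after the results had been seen, and the splits of group labels only after the counts were known.

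The averaged 1x effect overlapped between each pair of tissues. Primary meristem and flesh shared 56 higher genes, where 5.56 would be shared by independent draws (Fisher p = 1.2e-39), and 6 lower genes against 1.59 (Fisher p = 0.0053). Primary and secondary meristem shared 36 higher genes against 12.8 (Fisher p = 2.5e-08) and 19 lower genes against 11.4 (Fisher p = 0.030). Secondary meristem and flesh shared 63 higher genes against 14.3 (Fisher p = 1.6e-23) and 34 lower genes against 9.57 (Fisher p = 7.7e-11). Fisher's test treats genes as independent, which genes of shared function are not. The labels do not say whether the tissues came from the same tubers or store, so their samples may not be independent either. The overlap cannot then be assigned to DMN alone. In all 3 tissues 8 genes were higher and 1 lower, and no expected number was worked out for these. The DCD (Development and Cell Death) domain gene Soltu_DM_08G004800 was higher at log2 changes of 1.26, 1.31 and 0.77 in primary meristem, secondary meristem and flesh (adjusted p = 0.0015, 0.0040 and 2.2e-04). A WD40 repeat gene (Soltu_DM_05G010270; 0.92, 1.37 and 0.62), an A20/AN1-like zinc finger gene (Soltu_DM_01G027750; 0.70, 0.95 and 0.42) and a mitogen-activated protein kinase (Soltu_DM_06G005160; 0.91, 0.68 and 0.43) were higher, in the same order of tissues. SER/ARG-rich protein 34A (Soltu_DM_03G021660), an alpha/beta-hydrolase (Soltu_DM_09G023990), an aldolase-type gene (Soltu_DM_10G003260) and a further WD40 repeat gene (Soltu_DM_06G012100) were also higher in all 3. A Xanthine/uracil permease (Soltu_DM_03G027950) was lower at −0.91, −0.49 and −0.23.

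The added list of ribosomal protein genes was called in opposite directions in primary meristem and flesh. On average over weeks, 19 of 348 were lower and 1 higher in primary meristem (camera adjusted p = 3.7e-12, and adjusted p = 0.64 with an estimated correlation), and 20 of 340 higher in flesh (camera adjusted p = 2.0e-12, and adjusted p = 0.29 with an estimated correlation). During storage of controls, 83 of 348 rose in primary meristem (camera adjusted p = 1.0e-09, and adjusted p = 0.46 with an estimated correlation), while 204 of 340 fell and 38 rose in flesh (camera adjusted p = 2.6e-14, and adjusted p = 0.14 with an estimated correlation).

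One hypothesis was that DMN-treated primary meristem at week 12 shows less of the change that storage brings in controls. Genes changed by storage were chosen with 1 control library held out, so that it, like the treated libraries, was outside the comparison that chose them. Each held-out control was measured on its own set of genes, and each treated library as the mean over the 3 sets. In primary meristem 8 of 9 treated libraries had a smaller median change than the lowest held-out control. The treated libraries ran from 0.79 to 1.71 on the log2 scale and the held-out controls from 1.52 to 2.10. In secondary meristem 0 of 9 were below and 6 above the held-out controls (1.40 to 2.02 against 1.34 to 1.73), and in flesh 4 of 8 were below and 2 above (0.65 to 0.80 against 0.77 to 0.79). On each control's own genes, however, secondary meristem 2x replicate 3 lay below the held-out control (1.334 against 1.345, 1.396 against 1.531, and 1.477 against 1.729). The other treated libraries there lay above it, except 3x replicate 3 on 1 set (1.627 against 1.729). In flesh the 3x libraries ran from 0.651 to 0.692 over the sets, and those under 1x and 2x from 0.765 to 0.798. The values go with the hypothesis for primary meristem, and flesh under 3x also lay below its held-out controls. Whether the tissues differ in this was not tested, and 3 control libraries set each range.

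Group labels were exchanged between treated and control libraries of the same week and the tests repeated. In the averaged comparisons 1 of 60 splits, the real one, had as many calls as observed, and the highest of the others had 40 in primary meristem, 996 in secondary meristem and 162 in flesh. For the differences between tissues 1 of 40 did, and the highest others had 6 against flesh and 2552 against secondary meristem. Such splits remove the 1x effect in every tissue, so they do not single out a difference between tissues. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. There the real and the highest other counts were 4584 and 469 for primary meristem at week 12 under 1x, 2242 and 1118 under 2x, 2603 and 2 under 3x, and 835 and 6 for 3x against 1x. In secondary meristem at week 12 they were 4535 and 6, 3340 and 0, and 2900 and 1 under 1x, 2x and 3x, and in flesh 199 and 10 under 1x and 3097 and 2 under 3x.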
